A study of Rattus norvegicus with 3 samples.

How the data were processed

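Nuclei were isolated from rat brains with an extraction buffer and a discontinuous iodixanol gradient, and 1 library per treatment was made with 10x Genomics Next GEM 5' v2 chemistry and sequenced on an Illumina NovaSeq. Each library pooled the nuclei of 4 animals, and no assignment of nuclei to animals was given, so every comparison set 1 library against 1 library. The deposited matrices hold raw UMI counts per gene and barcode, with no normalisation by the authors. According to the submitters' processing notes, and per the file headers, the counts came from Cell Ranger 7.0.0, and the submitters' processing notes name the genome build mRatBN7.2. The annotation release, the cell-calling settings and gene positions were not given in the sources used here. The feature tables list 30560 features under 28370 names, of which 7162 carry only an Ensembl identifier and were not assigned a symbol, and genes are named by the symbols of those tables.

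The analysis used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9. The comparisons, gene lists, markers and settings below were chosen before the data were examined. Barcodes with at least 500 detected genes and at most 5% mitochondrial UMIs were kept, which left out 4092, 721 and 1885 barcodes of the saline, LPS and poly(I:C) libraries for few genes and 0, 7 and 0 for mitochondrial UMIs. Scrublet, run per library with its automatic threshold, then left out 4566 (21.4%), 553 (5.28%) and 1004 (7.66%) nuclei as doublets, against rates of 17.1%, 8.39% and 10.5% expected from 0.8% per 1000 nuclei. The kept nuclei held 23590944, 26778874 and 17855238 UMIs, with medians of 1224, 2499 and 1329 per nucleus. Counts were scaled to 10000 per nucleus and log-transformed, and 2000 variable genes were chosen over the libraries, leaving out genes of the response lists unless they were class markers. Clustering used 30 principal components, 20 nearest neighbours and the Leiden method at resolution 1, which gave 40 clusters.

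Clusters were named by hand from their leading genes and fixed markers of 18 cell types, of which 17 of 193 symbols were not found in the feature tables. In this way 13 classes were named, and 11 clusters stayed unnamed, holding 13.2%, 9.15% and 11.3% of the kept saline, LPS and poly(I:C) nuclei. Of 13 clusters named excitatory neurons, 3 had no excitatory marker at least 2-fold higher than in the other clusters but held Slc17a7, a vesicular glutamate transporter, at 103 to 140 CPM, against at most 10.1 CPM in inhibitory neuron clusters. The excitatory share was 49.5%, 41.6% and 47.5%, but 38.4%, 32.1% and 37.5% without these 3 clusters and 12.8%, 13.7% and 13.0% with classes by marker score, so it depends on how nuclei were named. Of the 11 unnamed clusters, 1 with endothelial and neuronal genes held 34, 83 and 127 nuclei, or 0.203%, 0.836% and 1.05%. In 3 others oligodendrocyte genes led, but Syt1 was found in 92.6%, 96.2% and 92.8% of their 780, 267 and 414 nuclei, 2 joined oligodendrocyte with neuron genes, 2 had cholinergic genes and no fixed class, and 3 had only a marker of an unrelated class among their top genes. Classes were compared when both libraries held at least 50 nuclei, except in the alternatives with thinning, with random parts or without Syt1-positive nuclei, which had no such minimum. Without Syt1-positive nuclei the saline, LPS and poly(I:C) libraries kept 30, 177 and 18 astrocytes, 42, 166 and 13 oligodendrocyte precursors, 22, 109 and 29 microglia or macrophages and 217, 137 and 84 endothelial nuclei. Fibroblasts (37, 48 and 24 nuclei) were not compared, and mature oligodendrocytes (91, 311 and 20), ependymal nuclei (66, 62 and 21) and choroid plexus epithelium (61, 50 and 8) were compared only between LPS and saline. No class of mural cells, T or NK cells or neutrophils was named.

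UMIs were summed over the nuclei of a class in a library and divided by that class's total. Ratios of these values carry exact conditional (Clopper-Pearson) 95% intervals, levels carry exact Poisson intervals and shares carry exact Clopper-Pearson intervals. These intervals cover neither animals nor preparation, so no significance test or p-value was computed, and counts of genes at least 2-fold apart describe these libraries only. A ratio against 0 counts is a lower bound computed with 3 counts in that library, and no ratio was computed when 1 count was 0 and the other 3 or fewer. Values given as at least a fold follow this rule and lie above the lower end of the exact 95% interval. The share of nuclei with a UMI was also computed after thinning each nucleus to 1000 UMIs, which left out 5387 saline, 1165 LPS and 2811 poly(I:C) nuclei with fewer UMIs. The LPS and the poly(I:C) comparison share the saline library, whereas the ratio of LPS to poly(I:C) does not use it.

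There were 22 fixed gene lists, 6 of them core lists: interferon-stimulated genes, class I antigen presentation, NF-kB targets, cytokines and chemokines, acute phase and STAT3 targets, and leukocyte adhesion. The others covered class II antigen presentation, complement, reactive astrocytes, homeostatic and activated microglia, the blood-brain barrier, innate sensors and adaptors, interferon and cytokine receptors, immediate early, glucocorticoid-induced, heat shock and unfolded protein, and oxidative stress and metallothionein genes, myelin, cholesterol synthesis, synapses and angiogenesis. Of 451 list symbols 38 were not found, and 46 of 53 interferon-stimulated symbols were found. Some genes stand on more than 1 list. A list was summarised in a class when at least 5 members had at least 10 UMIs over both libraries, as the median log2 ratio with 0.5 counts added per library, and again with genes at 0 counts set to their bound. The counting interval of a median came from 1000 Poisson resamples. A gene with 0 counts in a library stayed at 0 in every resample, so these intervals leave out the counting error of such genes. Each median was set against 10000 random lists of the same size matched on expression in 20 bins, which describes these libraries because genes are not replicates. Under this measure the interferon-stimulated median lay at percentile 99.99 in LPS excitatory neurons and 88.7 in LPS inhibitory neurons, and the leukocyte adhesion median lay at percentile 61.5 in LPS endothelial nuclei.

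Named genes followed a fixed rule. For each treatment against saline, the class with the largest absolute median of a core list gave the 3 members whose interval bound lay farthest from a ratio of 1, and each other list gave 1 member in the same way. In the endothelial, microglia or macrophage, astrocyte, oligodendrocyte, oligodendrocyte precursor, excitatory and inhibitory neuron classes, the 2 highest and the 1 lowest genes with at least 30 UMIs were added by the same bound. For LPS against poly(I:C), each core list gave 1 gene in each direction. Tlr4, Tlr3, Ifih1, Ifnar1 and Cd14 were followed in every class, and a gene named in 1 class was also read in others.

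The median log2 ratio over all genes of a class lay within 0.1 of 0 except for endothelial nuclei after poly(I:C), at -0.13, and oligodendrocytes after LPS, at 0.105, where median-of-ratios size factors differed from total counts by -0.15 and 0.13. For astrocytes in LPS over poly(I:C) the size factors differed by 0.10. Alternatives were 200 or 1000 detected genes, no doublets left out or doublets at 0.8% per 1000 nuclei, classes by marker score, response genes kept among the variable genes, median-of-ratios size factors, the mean of the nuclei's own values, thinning, 1 or 30 UMIs per member, 2 counts added, 5% or 10% of UMIs subtracted as free RNA at the library's mean profile, and random splits of each library into 2 parts. After seeing the data, 4 were added: the unnamed cluster with endothelial and neuronal genes counted as endothelial, the 3 unnamed clusters led by oligodendrocyte genes counted as oligodendrocytes, the 3 excitatory clusters without such a marker left unnamed, and Syt1-positive nuclei left out of glial and vascular classes. The procedure was tested on simulated data at the depth of these classes. In LPS endothelial nuclei, intervals excluded a ratio of 1 for 81.0% of 42 genes simulated at 2-fold and for 100.0% of 50 genes at 4-fold. At the poly(I:C) endothelial depth these were 71.4% of 35 and 100.0% of 45 genes. Free RNA was not measured, since only called barcodes were used here.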

Results

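Gene expression was measured in single nuclei from the brains of female Crl:CD(SD) rats, an outbred Sprague Dawley stock, aged 12 weeks. Brains were taken 7 hours after an intraperitoneal injection of saline, of lipopolysaccharide (LPS) at 5 mg/kg or of poly(I:C) at 12 mg/kg. LPS is a cell wall component of Gram-negative bacteria that is sensed by Tlr4, and poly(I:C) is a synthetic RNA duplex that stands in for viral RNA and is sensed by Tlr3 and Ifih1. Nuclei of 4 animals were pooled per treatment, which gave 3 libraries with 1 library in each group. The libraries held 25435 barcodes with 35532360 UMIs after saline, 11211 barcodes with 29763787 UMIs after LPS and 15001 barcodes with 21340578 UMIs after poly(I:C). The median barcode carried 1165, 2436 and 1264 UMIs in that order. Depth differed by class, with medians of 1336, 3101 and 1497 UMIs in excitatory neurons but 1031, 851 and 1308.5 in astrocytes. After filtering, 16777 saline, 9930 LPS and 12112 poly(I:C) nuclei were kept and sorted into 13 named classes. With 1 library per treatment, no difference below has a replicate check, and intervals in brackets are 95% intervals that cover counting error only. Those of list medians leave out the counting error of genes without a UMI in 1 of the libraries. Medians with such genes set to their bound can therefore lie outside these intervals. Values are given as ratios of CPM, a gene's UMIs scaled by all UMIs of the nuclei of a class, and list medians as median log2 ratios over the measured members of a gene list.

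The comparison of LPS with saline asked which brain cell classes differed after a bacterial stimulus given outside the brain. After LPS, endothelial nuclei had higher levels of chemokine, NF-kB target, acute phase and antigen presentation genes, while the median of blood-brain barrier genes was lower. This class also held mural and fibroblast markers, and no mural class was named, so its values cannot be assigned to endothelial cells alone. At least 2-fold higher than in other clusters were 9 endothelial, 7 mural and 5 fibroblast markers in its saline cluster. In its treated cluster these were 9, 9 and 4. The median log2 ratio of the NF-kB targets was 3.31 [2.45 to 4.24] in endothelial nuclei, 1.36 [1.01 to 2.38] in microglia or macrophages and -0.05 [-0.22 to 0.07] in excitatory neurons. For interferon-stimulated genes the median was 1.77 [1.70 to 2.23] in endothelial nuclei and 0.24 [0.09 to 0.50] in excitatory neurons. It was 0.12 in inhibitory, 0.29 in other and -0.21 in striatal projection neurons, with counting intervals that did not exclude no difference. Slco1c1, a thyroid hormone transporter of the blood-brain barrier, was 121.5-fold lower [41.3 to 591] in endothelial nuclei, with 517 UMIs after saline and 3 after LPS. It was the leading gene of the saline endothelial cluster, so the make-up of the class was not separated from expression. Over all barcodes, with no class used, it was at 0.08115-fold [0.06346 to 0.1024], with 1118 saline and 76 LPS UMIs.

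Of 36 measured interferon-stimulated genes, 33 were at least 2-fold higher in endothelial nuclei and none at least 2-fold lower, with a median of 1.83 when genes at 0 counts were set to their bound. In excitatory neurons 6 of 32 were at least 2-fold higher and 2 at least 2-fold lower, with a median of 0.25 at the bound. In endothelial nuclei, 11 of 15 measured cytokines and chemokines were at least 2-fold higher after LPS and 2 were at least 2-fold lower, with a median of 2.88 [2.17 to 4.99], or 2.99 at the bound. Cxcl11 and Cxcl10, ligands of Cxcr3, a chemokine receptor of T cells, had 0 UMIs after saline and 673 and 143 after LPS, which made them at least 318-fold and at least 67.6-fold higher. Cxcl9, a ligand of the same receptor, was 674-fold higher [120 to 26670] from 1 saline UMI. Of 23 measured NF-kB targets, 21 were at least 2-fold higher and none was at least 2-fold lower (median at the bound 2.71). The neutrophil attractants Cxcl1 and Cxcl2 were at least 44.9-fold and at least 28.8-fold higher, and Sod2, the mitochondrial superoxide dismutase, was 25.1-fold higher [16.01 to 41.6]. Among acute phase and STAT3 targets, 16 of 18 were at least 2-fold higher, with a median of 2.53 [2.36 to 3.10] and 2.56 at the bound. Lcn2, an iron-binding acute phase protein, was 113-fold higher [30.7 to 939], Fgl2, a fibrinogen-like protein, was 216-fold higher [38.1 to 8573], and Cebpb, a transcription factor of the acute phase, was 26.6-fold higher [9.97 to 100.2].

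Antigen presentation through class I was higher in the same nuclei, with 12 of 14 measured genes at least 2-fold higher and a median of 2.80 [2.23 to 3.01], or 2.83 at the bound. Nlrc5, the transactivator of class I genes, was 35.5-fold higher [5.81 to 1456], and the immunoproteasome subunits Psmb10 and Psmb8 were 12.8-fold [5.09 to 41.2] and 11.6-fold [4.96 to 33.1] higher. Leukocyte adhesion genes were split, with 4 of 11 at least 2-fold higher, 2 at least 2-fold lower and a median of 0.10 [-0.16 to 0.76], the same at the bound. Ackr1, a chemokine-binding receptor of venules, and Sele, the endothelial selectin, had 0 saline UMIs and were at least 16.6-fold and at least 10.9-fold higher, and Vcam1, an adhesion molecule for leukocytes, was 21.3-fold higher [6.83 to 107]. Complement genes had a median of 2.79 [2.10 to 3.51], or 2.85 at the bound, with 6 of 8 at least 2-fold higher, and Cfb, a component of the alternative pathway, was 10.8-fold higher [7.29 to 16.4]. Interferon and cytokine receptors had a median of 0.85 [0.37 to 1.49], and Osmr, the oncostatin M receptor, was 5.19-fold higher [3.41 to 8.11]. Mt2A, a metallothionein, was 86.5-fold higher [29.1 to 424], in an oxidative stress and metallothionein list with a median of 1.48 [0.75 to 2.18]. The small heat shock protein Hspb1 was 4.12-fold higher [2.98 to 5.78], in a list of heat shock and unfolded protein genes with a median of 1.11 [0.81 to 1.48]. Blood-brain barrier genes had a median of -0.85 [-1.31 to -0.60], or -0.90 at the bound, with 7 of 16 at least 2-fold lower and 2 at least 2-fold higher. Slco1a4, a transporter of organic anions and a fixed endothelial marker, was 6.32-fold lower [4.93 to 8.22], and at 0.1804-fold [0.1548 to 0.2094] over all barcodes. In endothelial nuclei the median of the angiogenesis list was 0.51 [-0.03 to 1.05], that of the cholesterol synthesis list 0.31 [-0.07 to 0.79], that of the activated microglia list -0.20 [-0.30 to 0.61] and that of the innate sensors and adaptors 0.58 [0.18 to 1.26].

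Among glial and barrier classes, microglia or macrophages had a complement median of 1.61 [1.01 to 2.83], or 1.82 at the bound, with 7 of 10 genes at least 2-fold higher. At least 2-fold higher in this class's cluster than in other clusters were 12 oligodendrocyte, 8 microglia or macrophage and 3 oligodendrocyte precursor markers. Values of this class therefore cannot be assigned to microglia or macrophages alone. Itgam, a subunit of complement receptor 3, had 0 UMIs after saline and 130 after LPS, at least 10.8-fold higher. Itgam is also a fixed marker from which this class was named, so the make-up of the class was not separated from expression. Homeostatic microglia genes had a median of -0.46 [-0.94 to -0.15] with 3 of 8 at least 2-fold lower, and class II genes had a median of 0.88 [0.43 to 2.75], or 0.67 at the bound, where the protease Ctss was 1.59-fold higher [1.13 to 2.31]. In astrocytes Gfap, the intermediate filament of reactive astrocytes, was 15.2-fold higher [9.41 to 26.3] and the copper carrier Cp was 20.02-fold higher [3.41 to 808]. The same limit holds for Gfap, a fixed marker from which the astrocyte class was named. Glucocorticoid-induced genes had an astrocyte median of 1.26 [0.61 to 1.60], with 7 of 11 at least 2-fold higher and 2 at least 2-fold lower. Interferon-stimulated medians were 2.20 [1.64 to 3.35] in astrocytes, 1.86 [1.35 to 3.01] in oligodendrocyte precursors, 1.31 [0.94 to 2.26] in microglia or macrophages and 5.08 [4.49 to 5.44] in choroid plexus epithelium, and at the bound 1.53, 1.83, 1.33 and 2.50. With at least 1000 detected genes the astrocyte median was 0.955. In choroid plexus epithelium the 6 measured members had at most 1 saline UMI each, and the median was 2.76 with members counted down to 1 UMI and 1.79 with classes by marker score. Herc6, an interferon-induced ubiquitin ligase, was 63.8-fold higher [10.9 to 2573] there from 1 saline UMI. Usp18, which removes Isg15 from proteins, and Parp9 had 0 saline UMIs and were at least 5.88-fold and at least 5.43-fold higher. In ependymal nuclei, all 6 measured reactive astrocyte genes were at least 2-fold higher, with a median of 4.88 [4.18 to 5.67], or 3.70 at the bound, and Cp was 23.5-fold higher [10.4 to 65.9]. Vegfa, the vascular growth factor, was 8.25-fold higher [4.23 to 18.4] in oligodendrocyte precursors and 5.22-fold higher [1.36 to 44.5] in microglia or macrophages. In mature oligodendrocytes the myelin median was 0.40 [0.23 to 0.60], Prex2 was 4.41-fold higher [3.69 to 5.31] and Il1rapl2, which is expressed by neurons, was 22.1-fold lower [8.72 to 71.9], but at 0.889-fold with 3 unnamed clusters of oligodendrocyte genes added, a setting chosen after seeing the data.

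Neuronal RNA differed between the libraries in these glial and barrier classes. A UMI of Syt1, a synaptic vesicle gene of neurons, was found in 75.2% of saline and 32.7% of LPS astrocytes, in 81.7% and 62.5% of microglia or macrophages, and in 77.7% and 55.7% of oligodendrocyte precursors. The same shares were 80.3% and 54.0% in choroid plexus epithelium, 83.3% and 25.8% in ependymal nuclei and 52.7% and 21.2% in mature oligodendrocytes, against 31.5% and 24.7% in endothelial nuclei. The synaptic list had medians of -1.55 [-1.93 to -1.16] in ependymal nuclei and -1.22 [-1.47 to -0.87] in oligodendrocytes, and Gria1, a glutamate receptor subunit, was 7.91-fold lower [3.87 to 18.8] in ependymal nuclei. The Gria1 ratio turned direction with classes by marker score. Markers of other cell types were also present in these classes. In endothelial nuclei 11 mural markers summed to 6706 CPM after saline and 6134 after LPS, beside 9368 and 8543 for 8 endothelial markers including Slco1a4, 3 erythroid markers summed to 8796 and 4636, and 10 neutrophil markers were 11.05-fold higher [7.43 to 17.01] after LPS. In microglia or macrophages 12 oligodendrocyte markers were 1.38-fold higher [1.22 to 1.57] after LPS, at 2578 CPM against 1390 for the class's own 12 markers.

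In excitatory neurons, immediate early genes had a median of -0.68 [-0.89 to -0.55], with 4 of 18 at least 2-fold lower and none at least 2-fold higher. Klf2, a transcription factor of that list, was 4.87-fold lower [1.80 to 16.5] from 22 saline and 5 LPS UMIs. The cholesterol synthesis median was -0.42 [-0.50 to -0.31] with 0 of 17 genes past 2-fold, and the synaptic median was 0.05 [0.03 to 0.07]. Cxcl11 and Cxcl9 had 0 saline UMIs in these neurons and were at least 15.7-fold and at least 11.4-fold higher, at 3.74 and 2.73 CPM against 3142 and 2218 CPM in LPS endothelial nuclei. In inhibitory neurons Chat, the enzyme of acetylcholine synthesis, was 4.62-fold higher [1.91 to 13.5]. Tlr4 had at most 5 UMIs in any class and library, and Cd14, a co-receptor for LPS, at most 4, and no interval of their ratios excluded 1. Tlr3 had 0 saline and 16 LPS UMIs in microglia or macrophages, with a lower interval bound of 0.958 for the ratio. Ifnar1, a subunit of the interferon receptor, was at 0.548-fold [0.425 to 0.702] in endothelial nuclei and at 0.905-fold [0.797 to 1.03] in excitatory neurons.

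Endothelial nuclei made up 1.89% [1.69 to 2.11] of kept saline and 1.83% [1.58 to 2.12] of kept LPS nuclei, and they came from separate clusters, 1 with 317 saline and 1 LPS nuclei and 1 with 0 saline and 181 LPS nuclei, which was led by the response genes Ifitm3, Cxcl9 and Cxcl11. The unnamed cluster of endothelial and neuronal genes held a further 0.203% of saline and 0.836% of LPS nuclei. Named non-neuronal nuclei made up 6.75% [6.37 to 7.14] after saline and 17.8% [17.01 to 18.5] after LPS among nuclei with at least 500 detected genes, a filter that acts on libraries of unequal depth. In 3 unnamed clusters led by oligodendrocyte genes there were 4.65% [4.34 to 4.98] of saline and 2.69% [2.38 to 3.03] of LPS nuclei, with Syt1 in 92.6% and 96.2% of them, and the non-neuronal shares were 11.4% and 20.4% when these were counted. With at least 1000 genes the order of the non-neuronal shares turned (6.002% and 2.83%), but names were lost at that setting. Oligodendrocyte, differentiating oligodendrocyte, microglia or macrophage, fibroblast and choroid plexus classes held 0 nuclei in both libraries, and endothelial nuclei numbered 233 and 2. Astrocyte (0.833% and 1.07%, 59 and 80 nuclei) and precursor (1.31% and 1.44%, 93 and 108 nuclei) shares were still higher after LPS, with no interval computed. They lay closer together than with at least 500 genes, where they were 0.721% and 2.65% for astrocytes and 1.12% and 3.78% for precursors. The ependymal share turned (0.565% and 0.293%). The turned order therefore cannot be read as a change in composition. The oligodendrocyte precursor interferon median turned too (-0.075). Without Syt1-positive nuclei Gfap was 7.23-fold higher in astrocytes (177 LPS and 30 saline nuclei) and Itgam at least 2.71-fold higher in microglia or macrophages (109 and 22 nuclei). With 83 LPS and 34 saline nuclei of an unnamed cluster of endothelial and neuronal genes added, a setting that like the one without Syt1-positive nuclei was chosen after seeing the data, the endothelial interferon median was 1.18, and with 5% free RNA subtracted that of excitatory neurons was 0.027. With 2 counts added, microglia or macrophages had an interferon median of 0.576 and an NF-kB median of 0.705, and with at least 30 UMIs per member the endothelial cytokine and chemokine median was 7.765.

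**Figure D1:**
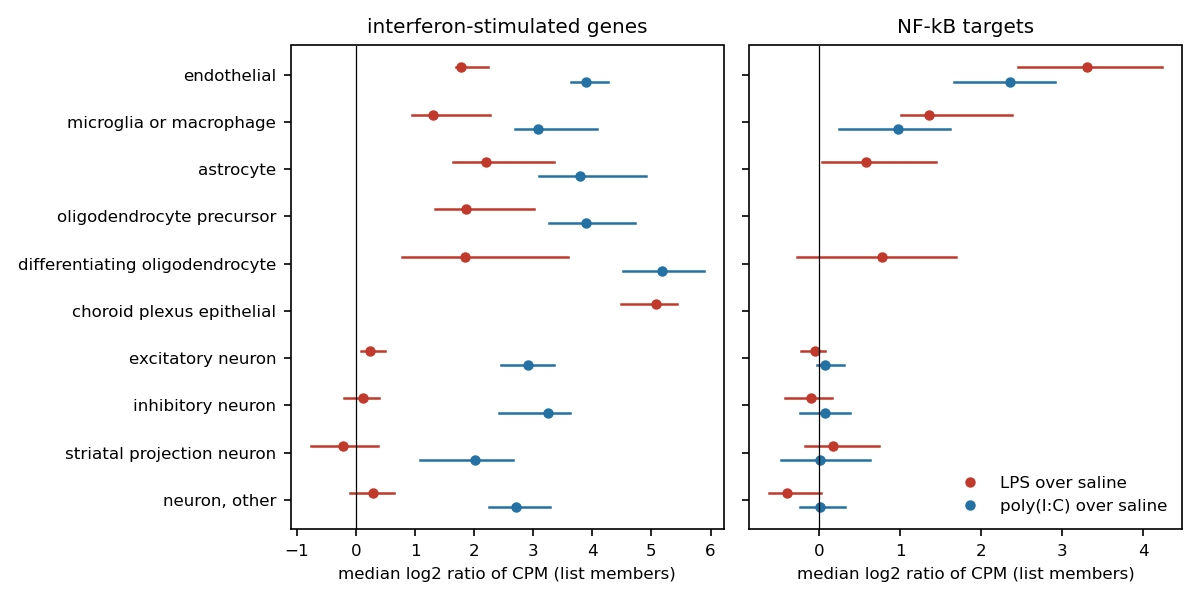
Median log2 ratio over saline of the interferon-stimulated list and of the NF-kB target list, by cell class, for the LPS and the poly(I:C) library, with bars for counting error. In excitatory neurons the interferon median was 0.24 after LPS and 2.92 after poly(I:C), and the NF-kB median of endothelial nuclei was 3.31 after LPS and 2.36 after poly(I:C). Each median covers the members measured in its own comparison, so the treatments are not shown over the same genes. The direct medians of LPS over poly(I:C) were -2.082 for the first list and class and 0.336 for the second.

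The comparison of poly(I:C) with saline asked the same of a viral RNA mimic. After poly(I:C), interferon-stimulated genes were higher in neurons as well as in glial and endothelial nuclei. Their median log2 ratio was 3.90 [3.63 to 4.27] in endothelial nuclei, 3.08 [2.69 to 4.08] in microglia or macrophages, 3.79 [3.10 to 4.91] in astrocytes and 2.92 [2.45 to 3.35] in excitatory neurons. In endothelial nuclei Cxcl11 and Cxcl10 had 0 UMIs after saline and 1362 and 1023 after poly(I:C), at least 1043-fold and at least 783-fold higher. Slco1c1 was 75.02-fold lower [25.5 to 365] in the same nuclei, and at 0.03723-fold [0.02399 to 0.05525] over all barcodes.

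Of the measured interferon-stimulated genes, 39 of 40 were at least 2-fold higher in endothelial nuclei, 29 of 39 in excitatory neurons and 19 of 27 in inhibitory neurons, and none was at least 2-fold lower in those classes. Oligodendrocyte precursors had 18 of 20 at least 2-fold higher and 1 at least 2-fold lower, with a median of 3.89 [3.27 to 4.72]. Differentiating oligodendrocytes had all 16 at least 2-fold higher, with a median of 5.17 [4.52 to 5.89]. The medians were 3.25 [2.42 to 3.62] in inhibitory neurons, 2.01 [1.09 to 2.66] in striatal projection neurons and 2.71 [2.25 to 3.29] in other neurons, and that of striatal projection neurons was 0.773 with at least 30 UMIs per member. At the bound for genes with 0 counts the medians were 3.97 in endothelial nuclei, 2.76 in microglia or macrophages, 3.84 in astrocytes, 3.00 in excitatory neurons, 2.67 in inhibitory neurons, 3.64 in oligodendrocyte precursors, 3.69 in differentiating oligodendrocytes, 1.86 in striatal projection neurons and 2.60 in other neurons.

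In differentiating oligodendrocytes, Herc6 was 109.9-fold higher [19.3 to 4382], and the antiviral GTPases Mx1 and Mx2 were 80.2-fold [13.9 to 3211] and at least 18.7-fold higher. Mx1 was 113-fold higher [19.8 to 4499] in oligodendrocyte precursors, at least 19.2-fold higher in microglia or macrophages and at least 14.3-fold higher in astrocytes. Slfn4, a Schlafen family gene induced by interferon, had 0 saline and 133 poly(I:C) UMIs in microglia or macrophages, at least 28.7-fold higher. In inhibitory neurons Usp18 had 0 saline and 67 poly(I:C) UMIs, at least 30.4-fold higher, and in excitatory neurons it was 38.5-fold higher [22.7 to 71.0]. Ifih1, the cytoplasmic sensor of RNA duplexes, was 13.01-fold higher [8.74 to 20.1] in excitatory neurons, 8.85-fold higher [4.39 to 20.2] in other neurons, 10.1-fold higher [5.93 to 18.3] in endothelial nuclei and 23.2-fold higher [3.74 to 961] in oligodendrocyte precursors. Ifnar1 was at 0.453-fold [0.323 to 0.624] in endothelial nuclei and at 0.922-fold [0.801 to 1.06] in excitatory neurons. Tlr3 had at most 8 UMIs in any class of the poly(I:C) library.

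After thinning every nucleus to 1000 UMIs, Herc6 was detected in 97.7% [88.0 to 99.94] of poly(I:C) and 15.8% [9.34 to 24.4] of saline endothelial nuclei (98.4% and 13.2% before thinning). In oligodendrocyte precursors the thinned shares were 39.8% [30.9 to 49.3] and 2.63% [0.546 to 7.50] (51.3% and 2.66% before thinning), and in excitatory neurons 8.66% [7.89 to 9.47] and 2.78% [2.39 to 3.22] (12.99% and 4.13% before thinning). Cxcl11 was detected in 93.2% [81.3 to 98.6] of thinned poly(I:C) endothelial nuclei and in 0% [0 to 3.59] of the 101 saline ones. Its thinned share was 2.31% [1.91 to 2.77] in poly(I:C) excitatory neurons, where median depth before thinning was 1497 UMIs against 860.0 UMIs in endothelial nuclei. Mx1 was detected in 65.9% [50.1 to 79.5] of thinned endothelial nuclei, 29.7% [21.6 to 38.8] of thinned oligodendrocyte precursors and 1.10% [0.833 to 1.44] of thinned excitatory neurons after poly(I:C). The poly(I:C) endothelial nuclei came from a cluster without saline nuclei that was led by response genes such as Ifitm3. That gene was on no response list and was not left out of the variable genes. The endothelial shares were therefore not separated from how the class was formed.

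**Figure D2:**
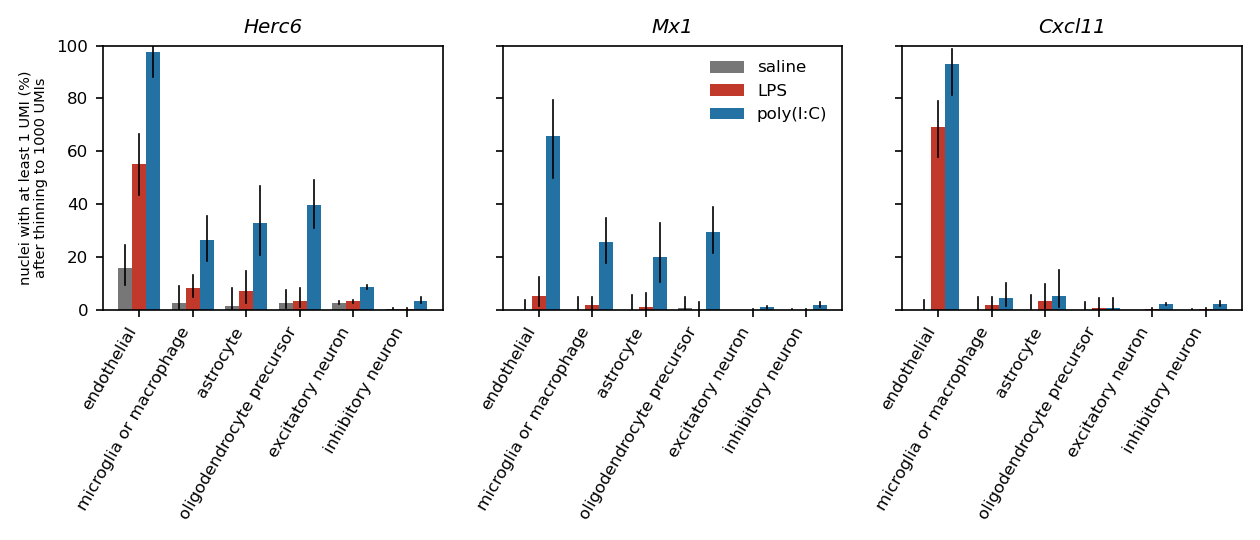
Percent of nuclei with at least 1 UMI of Herc6, Mx1 and Cxcl11 in 6 classes and 3 libraries after thinning to 1000 UMIs, with exact binomial intervals. Cxcl11 was found in 93.2% of poly(I:C) endothelial nuclei and 2.31% of poly(I:C) excitatory neurons, and Herc6 in 97.7% and 8.66%. The poly(I:C) endothelial nuclei came from a cluster led by response genes.

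In endothelial nuclei, class I antigen presentation genes had a median of 3.04 [2.38 to 3.26], or 3.09 at the bound, with 12 of 14 at least 2-fold higher. Nlrc5 was 82.7-fold higher [13.9 to 3356], Psmb8 28.3-fold higher [12.4 to 79.7] and Tap1, a peptide transporter subunit, 24.5-fold higher [7.67 to 125]. NF-kB targets had a median of 2.36 [1.67 to 2.91], or 2.43 at the bound, with 13 of 16 at least 2-fold higher. Ptgs2, the inducible prostaglandin synthase, was 49.4-fold higher [12.9 to 421], Birc3, an inhibitor of apoptosis, 59.7-fold higher [9.81 to 2449] and Sod2 23.1-fold higher [14.6 to 38.6]. Cytokines and chemokines had a median of 3.47 [2.65 to 4.50], or 2.94 at the bound, with 9 of 11 at least 2-fold higher and 1 at least 2-fold lower, and Cxcl9 was 841-fold higher from 1 saline and 366 poly(I:C) UMIs. Acute phase and STAT3 targets had a median of 2.69 [2.23 to 3.08], or 2.74 at the bound, with 15 of 17 at least 2-fold higher. Socs3, a feedback inhibitor of STAT3 signalling, was 31.4-fold higher [10.0 to 158.5] and Fgl2 223-fold higher [39.1 to 8891]. Leukocyte adhesion genes had a median of -1.01 [-1.43 to -0.41], or -1.08 at the bound, with 5 of 8 at least 2-fold lower and 1 at least 2-fold higher. Vcam1 was 14.6-fold higher [4.28 to 76.8], while Cd34, a sialomucin of endothelium, was 8.27-fold lower [2.14 to 70.8] and Alcam, an adhesion molecule of the immunoglobulin family, 2.59-fold lower [2.01 to 3.37].

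Blood-brain barrier genes had an endothelial median of -1.31 [-1.97 to -1.03], or -1.45 at the bound, with 10 of 16 at least 2-fold lower and 1 at least 2-fold higher, and Slco1a4 was 17.1-fold lower [10.4 to 30.1]. Over all barcodes Slco1a4 was at 0.08513-fold [0.06571 to 0.1087]. The innate sensors and adaptors had a median of 1.59 [1.04 to 2.40], and Ddx58, which encodes the RNA sensor RIG-I, was 16.4-fold higher [9.16 to 32.02]. Cfb was 15.1-fold higher [10.2 to 23.1], Mt2A was 60.5-fold higher [19.96 to 299.6], the chaperone Hsp90aa1 was 5.23-fold higher [3.94 to 7.003] and Il15ra, a subunit of the interleukin 15 receptor, was at least 9.19-fold higher. Across endothelial genes the median log2 ratio was -0.13, and these list values stand against that shift. Homeostatic microglia genes had a median of -1.02 [-1.40 to -0.34] in microglia or macrophages, with 4 of 8 at least 2-fold lower, and Selplg, a selectin ligand, was 8.51-fold lower [1.86 to 79.0]. Myelin genes had a median of -0.67 [-0.82 to -0.39] in differentiating oligodendrocytes, where Mbp, the myelin basic protein, was 1.69-fold lower [1.47 to 1.94]. Class I genes had a median of 1.19 [0.43 to 1.49] in excitatory neurons, with 6 of 11 at least 2-fold higher, whereas their NF-kB median was 0.07 [-0.03 to 0.31]. Immediate early genes had medians of -0.04 [-0.25 to 0.17] in excitatory neurons and -0.74 [-1.11 to -0.08] in other neurons, where Fos was 3.36-fold lower [1.08 to 13.8] from 16 saline and 4 poly(I:C) UMIs.

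Neuronal RNA was closer to the saline library than after LPS, with Syt1 UMIs in 75% of poly(I:C) astrocytes, 82.8% of microglia or macrophages, 57.4% of differentiating oligodendrocytes and 32.8% of endothelial nuclei, but 91.3% of oligodendrocyte precursors against 77.7% after saline. In endothelial nuclei mural markers were at 0.728-fold [0.665 to 0.796], the 8 endothelial markers, which include the lower Slco1a4, at 0.582-fold [0.535 to 0.632], erythroid markers at 0.419-fold [0.380 to 0.462] and neutrophil markers at 3.77-fold [2.31 to 6.27] of saline, and in microglia or macrophages oligodendrocyte markers were at 0.837-fold [0.718 to 0.977]. The endothelial synaptic median was 0.80 [0.50 to 0.98], and Camk2a, a kinase of synapses, was 3.91-fold higher [1.69 to 9.54] in endothelial nuclei but at 0.771-fold without Syt1-positive nuclei, a setting chosen after seeing the data.

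Endothelial nuclei made up 1.03% [0.860 to 1.23] of kept poly(I:C) nuclei and came from a cluster with 125 poly(I:C), 181 LPS and 0 saline nuclei, apart from the cluster of saline nuclei. The unnamed cluster of endothelial and neuronal genes held 127 more poly(I:C) nuclei (1.05%), against 34 saline nuclei (0.203%). The difference from the saline endothelial share of 1.89% therefore depends on how that cluster is named. With response genes kept among the variable genes, no poly(I:C) nucleus was named endothelial. Named non-neuronal nuclei made up 5.64% [5.24 to 6.07], a share that was 11.6% with at least 200 detected genes and 3.10% with at least 1000, and 9.06% with the 3 unnamed clusters of oligodendrocyte genes, which held 3.42% [3.10 to 3.76] of nuclei. With at least 200 genes the endothelial NF-kB median was 1.24, with all members counted down to 1 UMI the endothelial adhesion median turned to 0.21, and with 10% free RNA subtracted the excitatory neuron interferon median was 2.24. That subtraction used the library's mean profile, in which the interferon-stimulated list held 27466 of 21340578 UMIs. Barcodes with fewer than 500 genes held 6267 of 1007912, so free RNA richer in these genes would not be fully removed. Without Syt1-positive nuclei Mx1 was at least 9.08-fold higher in oligodendrocyte precursors and at least 5.46-fold higher in microglia or macrophages, but only 13 poly(I:C) and 42 saline nuclei of the first class and 29 and 22 of the second were left.

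**Figure D3:**
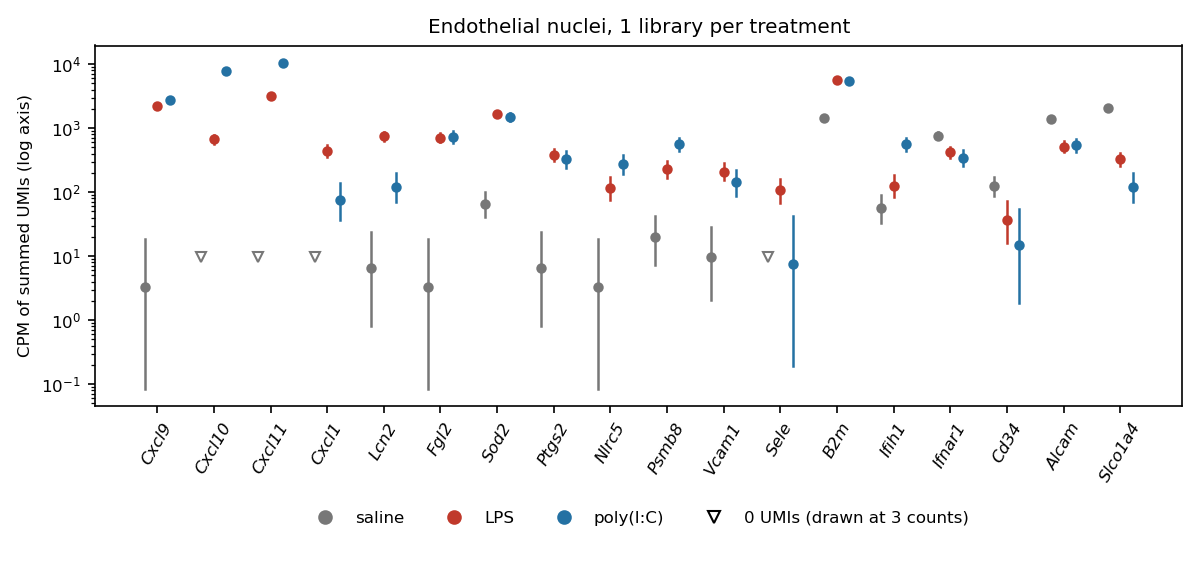
Levels of 18 genes in endothelial nuclei of the saline, LPS and poly(I:C) libraries in CPM on a log axis, with Poisson intervals and open triangles where no UMI was found. Cxcl10 stood at 668 after LPS and 7733 after poly(I:C), and Lcn2 at 742 and 121. Slco1c1, which is not among the genes drawn, stood at 14.01 and 22.7 against 1701 after saline.

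The direct comparison of LPS with poly(I:C) asked where the responses to the 2 stimuli differed. Interferon-stimulated genes were lower after LPS in every class with at least 50 nuclei in both libraries, with median log2 ratios from -2.93 [-3.68 to -2.53] in differentiating oligodendrocytes to -1.29 [-2.08 to -1.16] in astrocytes. In endothelial nuclei the NF-kB median was 0.34 [0.09 to 0.71] and the adhesion median 0.93 [0.39 to 1.32], both higher after LPS, and with thinning they were 0.0462 and 0.324, from 78 LPS and 44 poly(I:C) nuclei. Cxcl10 was 11.6-fold higher [9.72 to 13.9] after poly(I:C) in endothelial nuclei, and Lcn2 was 6.14-fold higher [3.67 to 11] after LPS.

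Of the interferon-stimulated genes, 37 of 41 were at least 2-fold lower after LPS in endothelial nuclei, 31 of 41 in excitatory neurons and 23 of 31 in microglia or macrophages, and none was at least 2-fold higher there. The medians were -1.82 [-2.15 to -1.69], -2.08 [-2.69 to -1.83] and -1.70 [-2.14 to -1.42], and -1.84, -2.12 and -1.70 at the bound, where differentiating oligodendrocytes were at -3.10 and astrocytes at -1.27. Mx1 was 237-fold higher [41.6 to 9457] after poly(I:C) in oligodendrocyte precursors, with 102 UMIs against 1. In endothelial nuclei Mx1 was 29.7-fold higher [15.3 to 66.1] and Herc6 5.44-fold higher [4.58 to 6.50] after poly(I:C), whereas Ifi27, an interferon-induced mitochondrial protein, was 1.40-fold higher [1.13 to 1.74] after LPS. Slfn4 was 5.17-fold higher [3.82 to 7.04] after poly(I:C) in microglia or macrophages.

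Chemokines were split between the stimuli in endothelial nuclei, with 4 of 14 cytokines and chemokines at least 2-fold higher after LPS and 5 at least 2-fold lower. Cxcl11 was 3.28-fold higher [2.99 to 3.599] after poly(I:C) and Cxcl9 1.25-fold higher [1.09 to 1.43], while Cxcl1 was 5.87-fold higher [3.06 to 12.6] and Cxcl2 4.71-fold higher [2.25 to 11.4] after LPS. Of 23 NF-kB targets, 7 were at least 2-fold higher after LPS and none at least 2-fold lower (median at the bound 0.37). Among adhesion genes 6 of 12 were at least 2-fold higher after LPS (median at the bound 1.02), and Sele was 14.2-fold higher [2.31 to 585] with 23 LPS UMIs and 1 poly(I:C) UMI. Acute phase and STAT3 targets had an endothelial median of 0.00 [-0.17 to 0.44] and an astrocyte median of 0.99 [0.53 to 1.89], or 1.30 at the bound, with 6 of 8 at least 2-fold higher after LPS in astrocytes. Reactive astrocyte genes had an astrocyte median of 1.58 [1.18 to 2.55], with all 5 measured genes at least 2-fold higher after LPS, and Gfap, also a marker from which the class was named, was 3.01-fold higher [2.30 to 3.99]. Class I genes had medians of -0.19 [-0.51 to -0.04] in endothelial nuclei and -0.68 [-1.06 to -0.43] in excitatory neurons. B2m, the light chain of class I molecules, was at 1.02-fold [0.934 to 1.13] in endothelial nuclei, and Tap1 was 35.8-fold higher [5.83 to 1471] after poly(I:C) in excitatory neurons from 24 UMIs against 1. In excitatory neurons Birc3 was 5.46-fold higher [1.44 to 30.5] and Osmr 4.22-fold higher [1.59 to 13.1] after poly(I:C), while in astrocytes Alcam was at 0.799-fold [0.609 to 1.06]. Blood-brain barrier genes had an endothelial median of 0.89 [0.40 to 1.38], with 6 of 13 at least 2-fold higher after LPS, and Slco1a4 was 2.70-fold higher [1.55 to 4.98] after LPS. Immediate early genes had a median of -0.78 [-0.997 to -0.557] in excitatory neurons, and myelin genes of 0.81 [0.613 to 1.002] in differentiating oligodendrocytes, with 4 of 14 at least 2-fold higher after LPS.

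Syt1 was found in 32.7% of LPS and 75% of poly(I:C) astrocytes, and synaptic genes had medians of -0.69 [-0.89 to -0.50] in astrocytes and -1.16 [-1.32 to -0.81] in differentiating oligodendrocytes. Without Syt1-positive nuclei the astrocyte acute phase median turned to -0.24, from 177 LPS and 18 poly(I:C) nuclei. After thinning, the astrocyte interferon median was -0.484. The endothelial medians of the class I and of the cytokine and chemokine lists turned to 0.051 and 0.14 when no doublets were left out.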

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

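For the patterns weighed here, the comparisons of Slco1c1 and Slco1a4 with other endothelial markers over all barcodes and the 2 comparisons with the share that the endothelial chemokines allow were chosen only after the result was seen, and the other tests before, although the setting without Syt1-positive nuclei was added after the data were seen.

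Interferon-stimulated UMIs were also present in barcodes and nuclei that the comparisons did not use, at levels above those in the saline library. In barcodes with fewer than 500 genes, their share of UMIs was 4.33-fold [3.796 to 4.95] that of saline after LPS and 27.5-fold [25.1 to 30.1] after poly(I:C). In the unnamed cluster of endothelial and neuronal genes the ratios were 2.40 [1.60 to 3.72] and 16.7 [11.4 to 25.4]. In nuclei called doublets they were 1.78 [1.65 to 1.93] and 5.13 [4.83 to 5.45].

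Lists with medians in opposite directions in 2 classes under the same comparison were listed too, and none of these differences between classes was tested. After LPS, the blood-brain barrier median was 1.09 in astrocytes and -0.85 in endothelial nuclei, and the interferon and cytokine receptor median was 0.85 in endothelial nuclei and -0.67 in striatal projection neurons. After poly(I:C), the immediate early median was 0.69 in endothelial nuclei and -0.74 in other neurons.

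The interferon-stimulated genes in excitatory neurons of the poly(I:C) library may be expressed there or may be free RNA from other cells. The list reached 1.58% [1.51 to 1.64] of its endothelial level in these neurons, above the endothelial markers at 0.491% [0.416 to 0.578] and the 3 chemokines at 0.194% [0.174 to 0.216]. The highest single marker, Ptprb, stood at 0.883% [0.700 to 1.11], and the list's excess over saline was 1.21% of the endothelial excess (no interval computed). These values argue against endothelial cells as the only source of the summed UMIs, but not for every member. UMIs in these neurons and in endothelial nuclei were 539 and 86 for Eif2ak2, 9 and 91 for Isg15, and 377 and 2751 for the 3 chemokines. Against the library's mean profile, the list stood at 44.0% of its level over all barcodes, between the bounds of 10% and 50% set for this test. Its summed excess over saline was 37.26% [35.9 to 38.6] of the excess over all barcodes, whereas the 3 chemokines stood at 11.4% [10.2 to 12.6], which argues against free RNA at that profile as the only source of the summed UMIs. For the median member, the excess of its CPM over saline in these neurons was 23.6% of the excess over all barcodes, with 28 of 38 members above the upper bound of the chemokines at 12.6% but a lower quartile of 12.3%, so free RNA stays open for the lower members and, as its profile was not measured, for another profile. For Cxcl9, Cxcl10 and Cxcl11 themselves, 0.194% of the endothelial level lies within the range of single endothelial markers, 0.115% to 0.883%, and fits free endothelial RNA.

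The lower Slco1c1 in endothelial nuclei of both treated libraries could reflect lower expression, a loss of the nuclei that express it, or neuronal RNA in the class. Over all barcodes, with no class used, the smaller gap between the median of 8 other endothelial markers and Slco1c1 was 3.13 on the log2 scale, with medians of -0.49 after LPS and -0.69 after poly(I:C) against -3.61 and -4.72 for Slco1c1, which argues against a loss of endothelial nuclei as the main cause. For Slco1a4 the gaps were 1.98 after LPS and 2.86 after poly(I:C), against the same bound of 2. In both libraries the lowest of these markers stood above either gene beyond the counting intervals, by at least 4.824-fold for Slco1c1 and 2.17-fold for Slco1a4, which argues against a loss of all endothelial nuclei alike as the only cause, while a loss of the subset that expresses these genes stays open. Those markers did not move together, since Cdh5 was at 1.62-fold and 3.59-fold and Cyyr1 at 0.474-fold and 0.388-fold. Without Syt1-positive nuclei the higher Slco1c1 ratio of the 2 libraries was 0.0162. Syt1 was found in similar shares of endothelial nuclei, 31.55% after saline, 24.73% after LPS and 32.8% after poly(I:C). Leaving out such a minority of nuclei could hardly have brought the ratio near 1, so this step cannot decide on neuronal RNA. No biological explanation beyond the treatment was tested, and treatment cannot be told apart from library.

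The interferon-stimulated genes in astrocytes of the LPS library may be higher because of the treatment, or because less neuronal RNA was mixed into these nuclei than in the saline library. The 11 astrocyte markers other than Gfap had a median log2 ratio of 0.76, with a range of 0.29 to 2.58, between the bounds set for this test, so the mixing stays open. Without Syt1-positive nuclei the interferon median was 1.71, from 177 LPS and 30 saline nuclei. A difference in depth could not be tested, because fewer than 5 members were left after thinning.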

How the results depend on the processing

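Counting the unnamed cluster of endothelial and neuronal genes as endothelial, counting the 3 unnamed clusters led by oligodendrocyte genes as oligodendrocytes, leaving 3 excitatory clusters unnamed and leaving out Syt1-positive nuclei were chosen after the results were seen, and the other alternatives before the data were examined. Over all alternatives, 1538 of 1717 list medians stayed within the counting interval of the reported value, 166 left it and 13 turned direction. Of 2374 gene ratios, 2089 stayed within their interval, 279 left it and 6 turned, and of 285 class shares 112 stayed within their interval and 173 left it. No paired analysis was possible because each treatment had 1 library of pooled animals. With 1000 detected genes, the endothelial, microglia or macrophage and differentiating oligodendrocyte classes gave no comparison, and thinning gave no interferon value for astrocytes in LPS over saline. Of genes simulated at 2-fold, 71.4% were separated from 1 at the poly(I:C) endothelial depth and 94.0% at that of excitatory neurons, and other classes were not simulated. For the values below, the cause was not tested.

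With 200 detected genes, the endothelial interferon-stimulated median was 3.21 for poly(I:C) over saline and -1.33 for LPS over poly(I:C), the endothelial NF-kB median was 2.41 for LPS and 1.24 for poly(I:C) over saline, and named non-neuronal shares were 9.06%, 23.6% and 11.6% after saline, LPS and poly(I:C). Endothelial medians for LPS over poly(I:C) turned to 0.075 for class I and to 0.10 for cytokines and chemokines. With 1000 detected genes the shares were 6.002%, 2.83% and 3.10%, but several non-neuronal classes held no saline or LPS nuclei at that setting. In oligodendrocyte precursors the interferon-stimulated median turned to -0.075 after LPS, with turned ratios of 1.32 for Mta3 after poly(I:C) and of 1.08 for Zfp804b, 0.190 for Ifih1 (1 LPS and 3 saline UMIs) and 0.627 for Fa2h after LPS.

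With no doublets left out, the endothelial interferon-stimulated median was 3.43 for poly(I:C) over saline and -1.37 for LPS over poly(I:C), and the shares were 8.39%, 19.2% and 7.10%. For LPS over poly(I:C), endothelial class I turned to 0.051, endothelial cytokines and chemokines to 0.14 and astrocyte cytokines and chemokines to -0.21. With doublets at 0.8% per 1000 nuclei the endothelial interferon-stimulated medians were 3.44 and -1.50, and for LPS over poly(I:C) endothelial class I turned to 0.047 and cytokines and chemokines to 0.021. With classes by marker score the endothelial interferon-stimulated median was 1.59 for LPS, 3.26 for poly(I:C) and -1.62 for LPS over poly(I:C), the endothelial NF-kB median after poly(I:C) was 1.49, and the shares were 36.6%, 37.97% and 32.2%. Gria1 in ependymal nuclei turned to 1.08-fold after LPS, and astrocyte cytokines and chemokines to -0.050 for LPS over poly(I:C). With response genes kept among the variable genes the poly(I:C) share was 4.40%, and its endothelial class held 0 nuclei, so poly(I:C) endothelial results had no value there. With unnamed oligodendrocyte clusters counted, the shares were 11.4%, 20.44% and 9.057%.

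With 2 counts added the endothelial interferon-stimulated median was 1.67 for LPS and 3.6 for poly(I:C). With members down to 1 UMI, cytokines and chemokines for LPS over poly(I:C) turned to 0.0045 in endothelial nuclei and to -0.10 in astrocytes, and endothelial adhesion after poly(I:C) turned to 0.21. With at least 30 UMIs per member the excitatory neuron interferon-stimulated median for LPS over poly(I:C) was -2.81 and the endothelial NF-kB median after poly(I:C) was 1.39, and with thinning the latter was 1.56. With 5% free RNA subtracted the excitatory neuron interferon-stimulated median after LPS was 0.027. With 10% it was 0.050 after LPS, 2.24 after poly(I:C) and -2.88 for LPS over poly(I:C). In 1 random part of each library the endothelial interferon-stimulated median after poly(I:C) was 3.57 and the NF-kB median after LPS was 2.41. With the unnamed cluster counted as endothelial, the endothelial interferon-stimulated median was 1.18 for LPS, 2.96 for poly(I:C) and -1.61 for LPS over poly(I:C), and the NF-kB median after poly(I:C) was 1.29. Without Syt1-positive nuclei the astrocyte acute phase median for LPS over poly(I:C) turned to -0.24, from 177 LPS and 18 poly(I:C) nuclei, and endothelial Camk2a after poly(I:C) to 0.771-fold. Without the 3 excitatory clusters the excitatory interferon-stimulated medians were 0.234, 2.89 and -2.07.

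Over all alternatives, interferon-stimulated medians after LPS ranged, in part from fewer than 50 nuclei, from 0.955 to 2.48 in astrocytes, 0.576 to 2.24 in microglia or macrophages, -0.0752 to 2.47 in oligodendrocyte precursors and 1.79 to 5.29 in choroid plexus epithelium. After poly(I:C) they ranged from 2.93 to 4.74, 2.25 to 4.05 and 3.02 to 4.91 in the first 3 of these, 3.03 to 6.16 in differentiating oligodendrocytes, and 1.98 to 3.29, 0.773 to 3.46 and 2.09 to 3.08 in inhibitory, striatal projection and other neurons. For LPS over poly(I:C) they ranged from -2.11 to -0.484 in astrocytes, -2.26 to -1.51 in microglia or macrophages and -4.17 to -2.34 in differentiating oligodendrocytes. Endothelial medians after LPS and after poly(I:C) ranged from 2.09 to 7.765 and 2.24 to 5.70 for cytokines and chemokines, 1.92 to 2.98 and 2.01 to 3.17 for class I, and 1.86 to 3.02 and 1.84 to 2.76 for acute phase genes, and for LPS over poly(I:C) from 0.0462 to 0.91 for NF-kB targets and 0.324 to 1.73 for adhesion genes. The NF-kB median of microglia or macrophages after LPS ranged from 0.705 to 2.28, and the class I median of excitatory neurons after poly(I:C) from 0.5 to 1.39.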

Other observations

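No test in this part was chosen after a result was seen, except the listing of single interferon-stimulated genes in excitatory neurons and the setting without Syt1-positive nuclei. Several genes named by the fixed rule lay outside the gene groups described for the main classes. After LPS, Grm8, a metabotropic glutamate receptor, was 3.72-fold lower [2.58 to 5.41] in astrocytes, Zfp804b was 3.47-fold lower [2.57 to 4.72] in oligodendrocyte precursors and Ppm1k was 3.79-fold lower [1.79 to 7.97] in microglia or macrophages. In oligodendrocyte precursors Fa2h, an enzyme of myelin lipid synthesis, was 3.73-fold higher [1.59 to 10.7] after LPS, and Ifih1 was 8.09-fold higher [1.27 to 338] from 1 saline and 17 LPS UMIs. With at least 1000 detected genes the precursor ratios of Zfp804b, Fa2h and Ifih1 all turned direction. In inhibitory neurons Col4a3, a chain of basement membrane collagen, was 3.53-fold lower [2.04 to 6.38] and Trhr, the receptor for thyrotropin-releasing hormone, 2.64-fold higher [1.55 to 4.70]. Irak2, an adaptor kinase of Toll-like receptor signalling, was 2.80-fold higher [1.25 to 7.36] and the tight junction gene Tjp1 1.498-fold higher [1.15 to 1.98] in astrocytes. Gfap had 0 saline and 74 LPS UMIs in microglia or macrophages, at least 6.13-fold higher and at least 2.39-fold higher without Syt1-positive nuclei (109 LPS and 22 saline), a class in which Syt1 was found in 62.5% of LPS nuclei. After poly(I:C), Snx29 was 4.58-fold lower [2.87 to 7.52] in microglia or macrophages, Alk, a receptor tyrosine kinase, 4.19-fold lower [1.75 to 12.2] in astrocytes, Mta3 3.42-fold lower [1.60 to 8.10] in oligodendrocyte precursors and Alg2 4.19-fold lower [1.86 to 11.1] in inhibitory neurons. The Mta3 ratio turned direction with at least 1000 detected genes. Nrp1, a receptor for Vegfa, was 2.67-fold higher [1.21 to 6.68] in microglia or macrophages.

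In excitatory neurons of the poly(I:C) library, single interferon-stimulated genes differed in level relative to the whole library, a listing chosen after the values were seen. The excess of a gene's CPM over saline in these neurons, as a percent of the same excess over all barcodes, was 77.9% for Eif2ak2, the RNA-dependent protein kinase, 76.1% for Stat2, 65.2% for Ifih1, 64.2% for Usp18 and 60.1% for Ddx58. It was 9.73% for Isg15, a ubiquitin-like modifier, 8.33% for Bst2, which tethers virions, and -3.94% for Isg20, the lowest of the 38 genes listed. Excitatory neurons held 9 Isg15 UMIs and endothelial nuclei 91, against 539 and 86 for Eif2ak2.

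Ifnar1 had 233 saline, 90 LPS and 46 poly(I:C) UMIs in endothelial nuclei and 495, 496 and 339 in excitatory neurons. Each treatment was 1 library, so effects of nuclei preparation or sequencing cannot be separated from effects of the treatment.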
